A study of Homo sapiens with 4 samples.

How the data were processed

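Total RNA from 2 independent cultures of U251 and 2 of UsiA12 was labelled with digoxigenin by reverse transcription and in vitro transcription and read by chemiluminescence, per the labels' protocols. The groups and replicate numbers were taken from the sample titles. Each of the 4 arrays held 37842 spots, of which 4746 were controls or blanks and 33096 were gene probes, each present once.

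The scanner table gives for every spot a signal, a signal to noise ratio, an assay normalized signal, a standard deviation, a coefficient of variation and a flag, per the file headers. The deposited signal was on a linear scale and already corrected for background, as judged from its values. On 25.8% of the gene probe spots it equalled its own standard deviation, and these were the spots with an odd flag. No further background correction was applied. The deposited signal to noise ratio is a score, the signal over its standard deviation before that replacement, and can be negative. The deposited assay normalized signal is an intensity equal to the signal divided by 1 of 2 factors per array, 1 factor for spot rows 1 to 119 and another for rows 121 to 239, as found by dividing one column by the other. The ratio of these factors ranged from 1.22 to 1.36 between arrays. The 4 columns of coefficients of variation were not used. The scanner software and its version are not given in the sources used here.

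The authors also deposited a value table with an intensity for 29585 of the gene probes, on a linear scale. Its ranks were those of the signal on every array, and its column medians were each 1274. The values differed from the quantile-normalized signal of the same probes by a median of -0.22 and by at most 0.30 in size on the log2 scale, so the exact step that made them stays unknown. The submitters' processing notes name limma, with no version. The table left out 3511 gene probes. Of these, 555 had a flag of 5000 or more on an array, a further 853 carried transcript in place of gene numbers, and for 2103 no reason was seen. The table was used only as an alternative source of values.

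The signal of all gene probes was quantile normalized between the 4 arrays and taken to log2 with limma 3.58.1 in R 4.3.3. Probes with a signal to noise ratio of at least 3 on at least 2 arrays were kept, which left 20639. They were tested with limma (lmFit and eBayes, two-sided, group means with no covariate) and Benjamini-Hochberg adjustment, with a threshold of 0.05. The fit had 2 residual degrees of freedom and 2.41 from the prior, and the median SE of a log2 fold change was 0.16. The number of arrays limits the precision. Where a probe was detected on both arrays of one line and on neither of the other, a bound of the fold was computed. It sets the mean log2 signal of the line with detection against the mean, per array, of the higher of the lowest detected signal and the probe's own signal. Where the probe's own signals were the higher, it equals the fitted fold. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

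The procedure was tested on simulated data with the replicate spread of these arrays, in which 200 of 20639 probes were changed by 1.5-, 2-, 4- or 8-fold in equal parts. It recovered 0% of the probes changed 1.5-fold, 0% of those changed 2-fold, 30% of those changed 4-fold and 56% of those changed 8-fold. Among its 43 calls, 0 were false. These shares do not give the recovery in the measured data. Few simulated probes were changed, which makes the adjusted threshold stricter, while 27.4% of the measured probes had an unadjusted p below 0.05. Each simulated probe also took the SD of a random probe of similar level, whether or not the filter kept it. The smallest log2 fold change called in the measured data was 0.88 in size.

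The scanner table names genes by Celera identifiers and a few accessions. These were looked up, without version numbers, in a table of RefSeq genes of assembly GRCh38.p14, of which only names were used. 81 of the 33096 probes were named, 70 by RefSeq accession and 11 by Celera number. 56 of the 81 were kept by the detection filter. The 494 genes of 16 lists that had been fixed before the data were examined (among them mitosis, DNA replication, cholesterol synthesis, extracellular matrix, interferon and cell type marker lists) could not be matched to a probe. The tests of these lists and of cell type markers were therefore not run. The gene targeted by the hairpin is not reported here, and the knockdown was not checked.

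The rule for genes to be named was also fixed before the data were examined. It took a few genes fixed by name, the 10 largest rises and falls among called probes detected on every array, the 5 largest bounds, and up to 4 members of each list. Where fewer than 10 passed, it went on to named probes that differed by at least 2-fold, given as values. With the names at hand, this gave SFRP1, HOPX, ZDHHC11 and OPLAH. The other genes named were chosen after their values were seen, as those with an unadjusted p below 0.05. The 4 Celera identifiers are the 2 largest rises and the 2 largest falls among called probes detected on every array.

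Alternatives fixed in advance changed the detection filter, the normalization, the source of values, an offset added before log2, the variance model, the treatment of flags, the threshold and a block for the replicate number, and left out each array in turn. Quantile normalization within each of the 2 parts of the rows was added after seeing the data, because the scanner software scales these parts separately.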

Results

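Gene expression was measured in U251, an established human glioblastoma cell line, and in UsiA12, a stable clone of U251. The clone was made by transfecting U251 with a plasmid that expresses a short hairpin RNA, together with the neomycin resistance plasmid pCI-neo. RNA from 2 independent cultures of each line was hybridised, which gave 4 chemiluminescent Applied Biosystems arrays with 33096 gene probes each. The comparison of UsiA12 with U251 asks which transcripts differ between the clone and its parental line. The clone was set against the parental line and not against a clone with an empty vector, so effects of the hairpin cannot be told apart from effects of cloning and selection.

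The arrays differed in overall brightness before normalization. The median signal of the gene probes was 1332 and 1159 on the U251 arrays, and 1453 and 1881 on the UsiA12 arrays. A signal to noise ratio of at least 3, the rule for detection, was reached by 60.3% and 57.0% of the gene probes in U251 and by 62.9% and 62.8% in UsiA12. After quantile normalization, log2 signals of the 20639 probes kept correlated across probes with r = 0.980 between the U251 cultures and r = 0.988 between the UsiA12 cultures. Across the lines, r ranged from 0.961 to 0.970. The SD of the log2 differences was 0.51 between the U251 cultures and 0.38 between the UsiA12 cultures, against 0.61 to 0.70 between arrays of different lines.

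SFRP1, a secreted protein that binds Wnt ligands, was the 1 gene with a known symbol that was called. Its normalized signal was 2.13-fold higher in UsiA12 (log2 fold change 1.09 ± 0.15, SE; limma adjusted p = 0.0464). Its log2 signal was 14.31 ± 0.01 (SD, n = 2) in U251 and 15.40 ± 0.18 (SD, n = 2) in UsiA12. The 3 other named genes that differed by at least 2-fold were also brighter in UsiA12, but did not pass the test. HOPX, an atypical homeodomain protein that does not bind DNA, was detected on both UsiA12 arrays and on neither U251 array, with a fitted signal 3.24-fold higher (limma adjusted p = 0.0825). OPLAH, the 5-oxoprolinase of the glutathione cycle, had the same detection pattern and a fitted signal 3.10-fold higher (limma adjusted p = 0.141). ZDHHC11, a member of the DHHC palmitoyltransferase family, was likewise detected only in UsiA12, with a fitted signal 2.80-fold above U251 (limma adjusted p = 0.129). The U251 signals of HOPX and ZDHHC11 were not detected but lay above the lowest detected signal, so that the bound equals the fitted fold and sets no firmer limit. For OPLAH this held on U251 replicate 1 alone, and the fold was 2.71 with U251 replicate 2 set to its lowest detected signal, which is no firm limit either. The values of all 3 genes rest on dim U251 signals that differed between the cultures. The log2 fold change of OPLAH was 1.00 without U251 replicate 2 and 2.31 without U251 replicate 1, that of ZDHHC11 0.94 and 2.09, and that of HOPX 1.24 and 2.19. A fit without U251 replicate 1 takes its spread from the UsiA12 cultures alone, so its p-values do not measure variation between U251 cultures. For HOPX, OPLAH and ZDHHC11 the SDs between cultures were 0.69, 0.99 and 0.84 in U251, and 0.19, 0.29 and 0.24 in UsiA12. HOPX passed on all 4 arrays with trended and robust variance estimation (limma adjusted p = 0.0159). With median scaling the log2 fold change was 1.12 for OPLAH and 1.11 for ZDHHC11. The call of SFRP1 was lost with any 1 of the 4 arrays left out, where its adjusted p ranged from 0.0719 to 0.230 and its log2 fold change from 0.96 to 1.22. It was also lost without the detection filter (adjusted p = 0.203), with median scaling (adjusted p = 0.0536) and with the scanner software's own normalization (adjusted p = 0.0518).

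Most probes carried identifiers that could not be matched to a gene symbol, and 56 of the probes tested, for 52 symbols, had one. Adjusted over these named probes alone, 0 passed in limma (smallest adjusted p = 0.0699), and 18 had an unadjusted p below 0.05, 8 higher and 10 lower in UsiA12. Among all 20639 probes tested, 27.4% had an unadjusted p below 0.05, so this cut does not set the named probes apart. The 14 probes of these 18 that are not described above were picked for mention after their values were seen. None passed the test over all probes as designed. With trended and robust variance estimation, where 4052 probes passed, all of these but WNT7B did. The limma adjusted p was then 0.000494 for GTF2I and 0.0588 for WNT7B. Some, GTF2I among them (limma adjusted p = 0.00781), also passed with detection required on all 4 arrays. GTF2I passed in 2 of its 16 alternatives. GTF2I, which encodes the transcription factor TFII-I, had a log2 fold change of -0.99 ± 0.16 (SE; limma adjusted p = 0.0587). Its relative GTF2IRD2 had a log2 fold change of -0.54, which was -0.34 without UsiA12 replicate 1 and -0.75 without UsiA12 replicate 2. The histone H4 gene H4C14 had a value of -0.69, and DALRD3, which takes part in tRNA modification, a value of -0.64. NOTCH2NLA, a partial duplicate of NOTCH2, was read by 2 probes with log2 fold changes of -0.48 and -0.55. NBPF15, of the neuroblastoma breakpoint family, stood at -0.51, the small GTPase gene RABL2A at -0.46, the centrosomal gene CEP170 at -0.41 and the Wnt ligand gene WNT7B at -0.42. On the other side, LCMT2, which takes part in tRNA modification, and FDXACB1 both had log2 fold changes of 0.51. The neutrophil defensin gene DEFA3 had a value of 0.63. ANAPC1, the largest subunit of the anaphase-promoting complex, had 3 probes that disagreed, with log2 fold changes of 0.66, 0.23 and -0.03. The value of 0.23 was 0.37 without UsiA12 replicate 1 and 0.09 without UsiA12 replicate 2. GTF2I, GTF2IRD2, NOTCH2NLA, NBPF15, RABL2A, CEP170, ANAPC1, ZDHHC11, H4C14 and DEFA3 have closely similar copies or family members in the genome. Their probes may read more than 1 gene, and their values are uncertain for that reason.

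**Figure D1:**
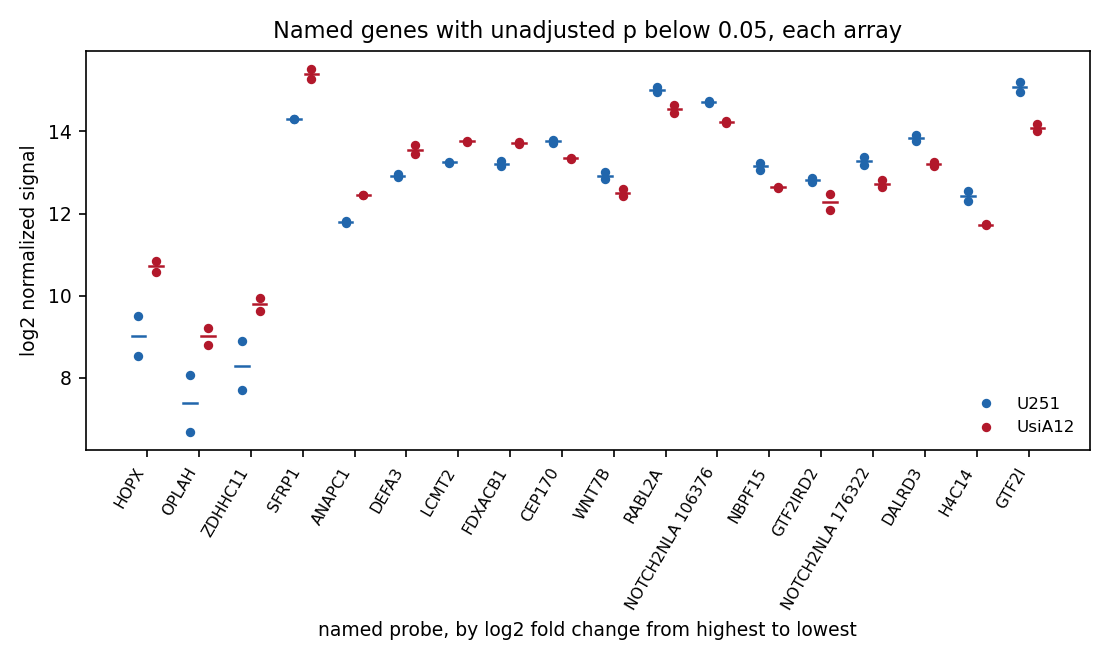
Log2 normalized signal (vertical axis) of the 18 named probes with an unadjusted p below 0.05 (horizontal axis, sorted by log2 fold change), with a point for each array, blue for U251 and red for UsiA12, and a bar at each mean (n = 2). SFRP1 lies at 14.31 in U251 and 15.40 in UsiA12, and the U251 points of HOPX, OPLAH and ZDHHC11 were below detection.

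Among all 20639 probes tested, 610 (2.96%) differed between UsiA12 and U251 in limma at an adjusted p below 0.05, with 281 higher and 329 lower in UsiA12. They carried 587 different gene identifiers, and the median size of their log2 fold changes was 1.44. At least 2-fold change was seen for 560 of them, 256 higher and 304 lower. Changes of at least 8-fold were seen for 21 probes that were higher and 20 that were lower. Of the 610 probes, 120 were detected on both arrays of one line and on neither of the other, 13 of the 21 and 8 of the 20 among them, and their folds are set against signals that were not detected. On 25.8% of all gene probe spots the deposited signal equalled its own standard deviation. How many of the undetected signals of these 120 probes this concerns is not given here. Over the 490 other probes, 164 were higher and 277 lower by at least 2-fold, 8 higher and 12 lower by at least 8-fold, and the median size of the log2 fold changes was 1.32. The largest rise among called probes detected on every array was that of hCG16372.3, 35.4-fold higher in UsiA12 (log2 fold change 5.15 ± 0.16, SE; limma adjusted p = 0.0132), with SDs of 0.09 in U251 and 0.21 in UsiA12 between the cultures (n = 2 each). It was followed by hCG33813.3, 9.01-fold higher (limma adjusted p = 0.0196). The largest fall was that of hCG39697.3, whose log2 signal was 17.59 ± 0.24 (SD, n = 2) in U251 and 11.15 ± 0.36 (SD, n = 2) in UsiA12, 86.8-fold lower (limma adjusted p = 0.0140). It was followed by hCG40511.3, 26.4-fold lower (limma adjusted p = 0.0132). No symbol could be paired with these 4 Celera gene identifiers.

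The number of calls and their balance rested on the arrays and settings used. With limma it was 0 without UsiA12 replicate 1 (3612 probes at an unadjusted p below 0.05), 0 without UsiA12 replicate 2 (3084 probes) and 62 without U251 replicate 2. It was 0 without the detection filter (5218 probes at an unadjusted p below 0.05), 2832 with detection required on all 4 arrays and 4052 with trended and robust variance estimation, while 5657 probes (27.4%) had an unadjusted p below 0.05 in the test as designed. Median scaling gave 225 probes higher and 359 lower, trended and robust estimation 2122 higher and 1930 lower, leaving out U251 replicate 1 440 higher and 203 lower, and leaving out U251 replicate 2 41 higher and 21 lower.

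**Figure D2:**
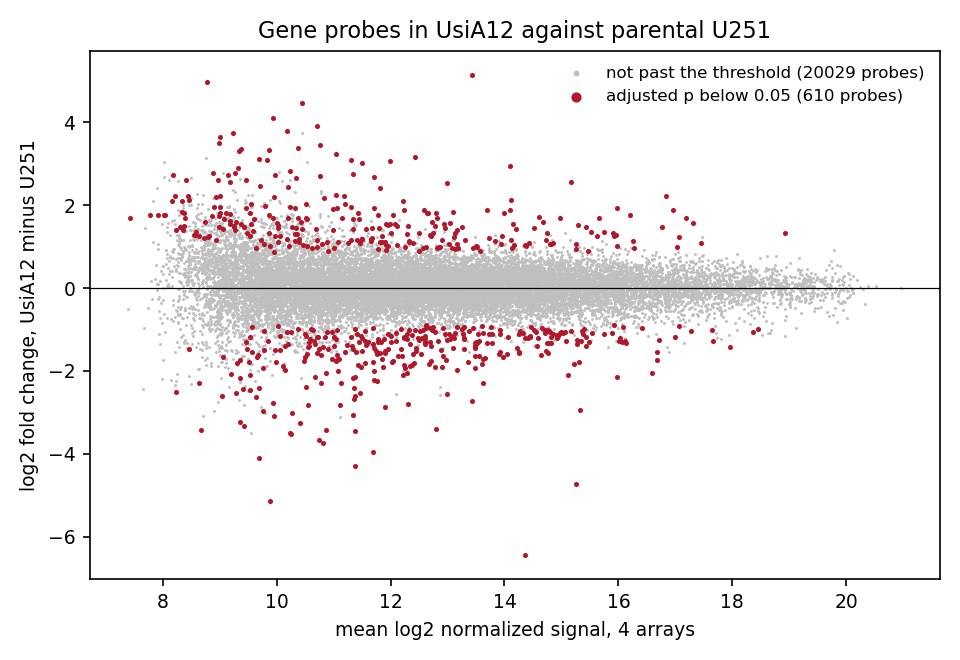
Log2 fold change of UsiA12 against U251 (vertical axis) against the mean log2 normalized signal of the 4 arrays (horizontal axis), with a point for each of the 20639 probes tested. The 610 probes with an adjusted p below 0.05 are red, 281 above and 329 below the line at 0, and the remaining probes are grey.

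More probes were detected in UsiA12 alone than in U251 alone. 715 probes were detected on both UsiA12 arrays and on neither U251 array, and 157 showed the opposite. The other 2 ways of splitting the arrays into pairs, which each put an array of both lines on either side, gave 139 and 266 such probes, and 122 and 293, so the 157 lay within what these splits gave and the 715 above it. Of the first set, 92 were among the 610 probes called, and of the second, 28. The UsiA12 arrays were brighter by 0.41 on the log2 scale in the median of the gene probes. Whether this accounts for the larger number detected in UsiA12 was not tested. Of the U251 arrays, the brighter one (median 1332 against 1159) had more probes detected (60.3% against 57.0%). Of the UsiA12 arrays, the brighter one (median 1881 against 1453) did not (62.8% against 62.9%). In means over 2 arrays, the control transcripts added at the labelling steps differed less, by -0.11 to 0.21 on the log2 scale. The positive control spots were brighter in UsiA12 by 0.57 and the hybridization controls dimmer (-0.27). These means hide a spread between the UsiA12 arrays for some controls. The control labelled IVT3 stood at 79091 and 120503 in UsiA12, and at 89776 and 79381 in U251. RT3 was closer, at 3331 and 3200 in UsiA12, and at 3804 and 3249 in U251.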

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

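The 610 calls kept their direction, wherever they were tested, under the 10 alternatives that change the fold changes (the other 6 leave them as they are). They were selected on these same arrays, with log2 fold changes of at least 0.88 in size, so a change of sign was hardly possible. The kept direction is therefore no evidence of robustness. The number of calls did not hold. It was 0 with no detection filter (5218 at an unadjusted p below 0.05 in limma) and 0 at an adjusted p below 0.01. With detection on all 4 arrays it was 2832. Fewer probes were then tested, and the 431 of the 610 among them were all called again. With trended and robust variances the number of calls was 4052. With an array left out it ranged from 0 to 643. Leaving out U251 replicate 1 gave 643 calls, 68.4% of them higher against 46.1%, with 305 shared, and leaving out U251 replicate 2 gave 62. In these fits the lone sample is assumed to vary like the other line. Median scaling, cyclic loess, the software's normalized values, the authors' values, an offset of 64 and the flag filter gave between 473 and 897 calls. Normalization within the row parts, chosen after seeing the data, gave 688. With the replicate number as a block it was 0 (4735 unadjusted), and SFRP1 had an adjusted p of 0.105 (0.000182 to 0.230 over its alternatives). Deviations of same-numbered cultures correlated at -0.04 across probes, and the labels do not say that a number marks a shared experiment. For the named genes, no sign could turn under the 6 alternatives that leave the fold changes as they are. All but SFRP1 were not called at the start, so settings with 0 calls could not move them past the threshold. The count of kept values is thus in part fixed in advance. Of 316 values of named genes, 277 kept direction and side of the threshold, 9 (all SFRP1) lost the call, 26 gained one and 4 turned sign. These 4 were the ANAPC1 probe at -0.03, which stood at 0.072 with the software's normalized values, 0.0029 within the row parts, and 0.10 without U251 replicate 2 and 0.046 without UsiA12 replicate 1 in a range of -0.15 to 0.10 with an array left out. Without the filter, replicate correlations were 0.971 (U251) and 0.979 (UsiA12), with more dim probes included. The cause was not tested for the other changes. Alternatives for the gene lists were not run, since their genes could not be matched to probes. The median SE was 0.24 over the 6880 dimmest probes and 0.15 over the 6880 brightest, while 3.60% of the first and 2.08% of the second were called.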

Other observations

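The patterns below were noticed in the data and then tested on the same data, so each is a hypothesis. The test of spot position for Celera numbers 6 to 20 apart was chosen after its result was seen.

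Probes that share a gene identifier gave a check on the fold changes that needs no gene names. Over 2005 identifiers with 2 probes tested, the log2 fold changes of the probes correlated with r = 0.491, against at most 0.068 in 1000 random pairings. These are correlations across probes, which are not independent replicates. The same pairs correlated with r = 0.048 and 0.128 in the differences between replicate cultures of U251 and UsiA12. Of 107 called probes with a partner, 90 had a partner with a change in the same direction. A pair with both probes called enters this count once for each probe. There were 18 such pairs, and in 17 of them the directions were the same. The value of 0.491 argues against noise of single spots as the sole source of the fold changes, and leaves a large part of them specific to a probe. It does not separate the hairpin from cloning, selection or any other difference between the cultures of the 2 lines.

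Genes with nearby Celera numbers had slightly similar fold changes. Over 17174 genes, r was 0.066 for numbers 1 apart, 0.055 for numbers 2 to 5 apart and 0.0135 for numbers 6 to 20 apart, all small. For numbers 1 to 20 apart whose spots lay at least 20 rows or columns apart, r was 0.0250, above the highest of 1000 random orders (0.0104), which argues against position on the array as the whole source. For numbers 6 to 20 apart, r was 0.0135 over all pairs and 0.0135 over such spots, which made up 96.4% of the pairs. It did not fall towards 0 (SD of random orders over all pairs 0.0040). The rule for this test, an r above every random order over such spots (highest 0.0142), was not met. The test therefore cannot decide whether closeness of the spots was its source. The excess over the larger replicate difference, 0.0175, decides nothing about batches, since a batch shared by same-numbered cultures cancels between the lines and one that goes with a line stays open. Split gene models that read the same RNA and neighbouring genes that change together cannot be told apart here, as both allow an r near 0 (-0.00066) for numbers 21 to 100 apart.

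The direction of the calls differed between the 2 parts of the array rows. In the first part, 41.4% of 324 calls were higher in UsiA12, against 51.4% of 286 in the second (Fisher's exact test, two-sided, p = 0.0146). This test treats probes read on the same 4 arrays as independent, so its p-values do not measure variation between arrays or cultures. With normalization within each part the shares were 45.9% and 47.5% (Fisher's exact test, p = 0.702). That normalization centres each part by itself and would even out the shares whatever their source, so a difference in signal scale between the parts stays open. 587 of the 610 calls were kept under that normalization. No biological explanation was tested.

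The log2 differences between the lines had an SD of 0.57 across probes, against 0.31 and 0.32 for the 2 other ways of splitting the 4 arrays into pairs. The 3 splits are too few for a share below 0.05.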
